A study of Arabidopsis thaliana with 8 samples.

How the data were processed

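RNA was measured in 8 libraries from Arabidopsis seedlings, 2 in each of 4 groups. Per the labels, total RNA was extracted with TRIzol and made into strand-specific libraries. The submitters' notes name CASAVA, STAR 2.5.3a, HTSeq 0.9.1, DESeq2 1.14.1 and the genome build TAIR10, without saying what each was used for. Whether counting used the strand, and how reads with several matches were treated, is not stated.

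The deposited table holds a signal for each locus and library. It has 64512 loci, of which 33323 are gene loci and 31189 are transposable element loci. In every library, 100% of the nonzero values were whole multiples of the smallest nonzero value (tolerance 0.001), so each value is a read count divided by a factor shared by all loci of the library. The median-of-ratios factor of the deposited values was 0.998 in all 8 libraries, so the libraries share a joint scaling of the kind DESeq2 gives. A value is called scaled reads in what follows. Read counts were recovered for 7 libraries. For LHS replicate 1 the step between values is too close to 1 to tell the division from rounding, so no read count is given for it and tests that need counts left it out.

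Gene loci were matched by identifier to the TAIR10.1 annotation, which held 32835 of them and gave a symbol for 10654. The annotation used here has no transposable element loci, so these were known only by identifier. No organelle loci are in the table. No genome positions are given.

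The values were analysed in R 4.3.3 with limma 3.58.1. Before the data were examined, the edgeR quasi-likelihood F test with TMM scaling was fixed as the main test for a table of counts. For a table without counts, limma-trend without robust estimation on log2 of the value plus 1 was fixed instead. All 8 libraries were to enter one fit, with each comparison as a contrast. The table held no counts, so limma-trend was used. Loci with a mean value of at least 1 were tested, which left 27638 (24624 gene loci and 3014 element loci). A locus is called when its adjusted p (Benjamini-Hochberg over all loci of the comparison) is below 0.05. The gene lists, the rule for named genes, the gene set test and most alternatives were fixed at the same time. Shares of calls among element and gene loci were compared with Fisher's exact test, two-sided. The other p-values are from limma, two-sided.

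There were 20 gene lists, with the element loci as a further set. They were small heat shock proteins, large chaperones, heat shock factors, the endoplasmic reticulum unfolded protein response, nuclear photosynthesis genes, chlorophyll synthesis, senescence, cell cycle, replication-coupled histone H3.1, silencing machinery, ONSEN copies, abscisic acid, reactive oxygen, salicylic acid, jasmonic acid and auxin responses, the circadian clock, and markers of root cell types, the stomatal lineage and seeds. Each was tested with camera at a preset correlation of 0.01, adjusted over 105 tests. It was run on log2 of the value plus 1 rather than on voom weights, since the table holds no counts. Fry, and camera with an estimated correlation, were the alternatives. None of the 67 list calls made with the preset correlation was made with an estimated one. Counts of list members called are given over all loci and adjusted over the list alone.

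Named genes in each comparison were the 5 called genes with the largest rise and the 5 with the largest fall among those with a symbol, an average log2 CPM of at least 3 and libraries that do not overlap. To these were added up to 2 risers and 2 fallers of each list, as far as 30 genes allowed, and HSP101, HSFA2, HSP21, HSA32, SDC and the ONSEN copies in each comparison with CTRL. Other members given as examples of a list were chosen after their values were seen, as was the division of the photosynthesis list into parts. Names of list members are those fixed with the lists.

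Depth was 18.9 M to 28.3 M reads at gene loci (M for 1e6) in the 7 libraries with recovered reads. For genes with 1 to 3 reads in CTRL, ratios have exact Clopper-Pearson 95% intervals computed from the reads. For genes at 0 in CTRL, a lower bound uses a floor of 3 reads per library. Intervals and floors cover counting error only. With changes added to simulated libraries, limma called 16% of 50 loci changed 1.5-fold, 58% at 2-fold and 100% at 4-fold and at 8-fold, with 15 false calls, 9.87% of all calls.

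Alternatives were a pseudocount of 0.1, no filter, an adjusted p of 0.01, a further minimum of 2-fold, only the 2 groups compared, the replicate number as a block, rRNA loci left out, and each library left out. After the data were seen, TMM scaling, scaling on gene loci alone, and edgeR 4.0.16 and DESeq2 1.42.0 on the reads of 7 libraries were added.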

Results

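RNA levels were measured in whole seedlings of Arabidopsis thaliana, accession Columbia, 7 days old by their label, in 4 groups of 2 libraries. CTRL was the control group. LHS seedlings were held at 37 °C for 30 h, and LHSR12 and LHSR84 seedlings were returned to 22 °C for 12 h or 84 h after that heat. Reads at gene loci numbered 18.9 M and 22.2 M in CTRL, 26.6 M in LHS replicate 2, 28.3 M and 28.1 M in LHSR12, and 19.3 M and 23.0 M in LHSR84. LHS replicate 1 had no recovered read count. The summed scaled reads of its gene loci were 25.4 M, within the range of 21.7 M to 26.9 M of the other libraries. The median absolute log2 difference between the 2 libraries of a group was 0.25 in CTRL, 0.16 in LHS, 0.16 in LHSR12 and 0.15 in LHSR84. The labels do not say whether the libraries came from separate cultures, so the p-values measure only the spread between these samples. They also give neither the time of day nor the age of the plants at harvest, so heat, recovery, age and time of day cannot be separated. Members of lists given as examples outside the rule for named genes were chosen after their values were seen.

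The series asks how RNA levels respond to long heat and to recovery from it, and the comparison of LHS with CTRL gives the state at the end of heat. Heat shock protein genes and copies of the heat-responsive retrotransposon ONSEN were among the loci with large rises. HSP21, a chloroplast small heat shock protein, went from 14.1 ± 2.76 scaled reads in CTRL to 62490 ± 11100 in LHS (SD, n = 2 each), a log2 fold change of 12.01 (SE 0.31, adjusted p = 1.04e-07, limma). HSFA2, a heat shock transcription factor, went from 14 ± 4.47 to 3201 ± 4.14 and HSP101, a disaggregating chaperone, from 364 ± 139 to 39020 ± 2898 (SD, n = 2 each). Among the largest falls was LHCB2.3, a light-harvesting protein of photosystem II, from 13380 ± 7701 to 39.3 ± 5.35.

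Of 16 small heat shock protein genes, 15 rose and 1 fell in LHS (adjusted over the list alone, 15 and 1), with a median log2 fold change of 9.11. HSP22-ER of the endoplasmic reticulum and mitochondrial HSP23.6-M rose by 11.45 and 11.02, and the faller was HSP15.4 at −1.46. The list was called by camera (adjusted p = 1.23e-07, and adjusted p = 0.401 with an estimated correlation). All 14 large chaperones and co-chaperones rose (adjusted over the list alone, 14) (camera adjusted p = 8.02e-07, and adjusted p = 0.443 with an estimated correlation). The immunophilin ROF2 was at 8.94 and HSP90.1 at 8.70. HSA32, which is needed for lasting acquired thermotolerance, rose by 6.67. Of 20 tested heat shock factors, 11 rose and 4 fell (adjusted over the list alone, 12 and 4), with HSFA2 at 7.77, HSFA3 at 4.85 and HSFC1 at −1.64 (camera adjusted p = 0.0195, and adjusted p = 0.415 with an estimated correlation). In the endoplasmic reticulum stress list, 14 of 18 rose (adjusted over the list alone, 14), among them the co-chaperone ERDJ3A at 5.23 and the transcription factor NAC103 at 5.15, while BZIP60 was at 0.10 and not called (camera adjusted p = 0.00107, and adjusted p = 0.504 with an estimated correlation). APX2, a cytosolic ascorbate peroxidase, rose from 6.32 ± 3.20 to 12900 ± 2582 (SD, n = 2 each).

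**Figure D1:**
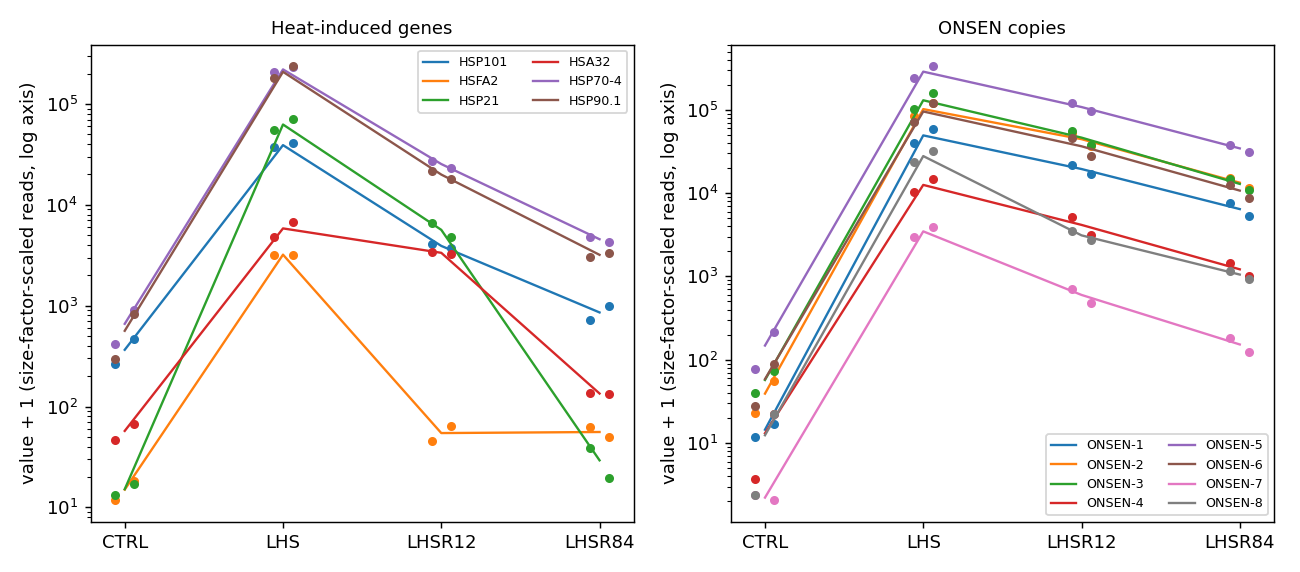
Scaled reads plus 1, on a log axis, of 6 heat-induced genes (left) and 8 ONSEN copies (right) in the 4 groups. Points are the 2 libraries of each group and lines join the group means. HSP21 falls from 62490 in LHS to 28.3 in LHSR84, while ONSEN-1 is at 49250 in LHS and still at 6422 in LHSR84.

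All 8 ONSEN copies rose in LHS, with a median log2 fold change of 11.13 (adjusted over the list alone, 8), and the list was called by camera (adjusted p = 5.69e-06, and adjusted p = 0.409 with an estimated correlation). ONSEN-1 went from 13.5 ± 3.72 to 49250 ± 13240 scaled reads and ONSEN-8 from 11.4 ± 14.2 to 27800 ± 6076 (SD, n = 2 each). ONSEN-7 had 2 reads over both CTRL libraries, and its ratio in LHS replicate 2 was 3310 (95% counting interval 916 to 27340). The copies are nearly identical in sequence, so how reads were shared among them is uncertain. SDC, an F-box gene silenced in unheated plants, rose by 2.85.

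Genes of photosynthesis fell as a group, 51 of 52 in LHS (adjusted over the list alone, 51), with a median of −2.38 (camera adjusted p = 4.76e-17, and adjusted p = 0.409 with an estimated correlation). LHCB2.3 and LHCB1.4 had the largest falls of the list, at −8.25 and −6.10. Of 15 chlorophyll synthesis genes, 14 fell (adjusted over the list alone, 14), such as PORB, which reduces protochlorophyllide, at −2.99 (camera adjusted p = 7.37e-05, and adjusted p = 0.362 with an estimated correlation). Root cell markers fell in 18 of 21 cases (adjusted over the list alone, 19), among them the iron transporter gene IRT1 at −6.09 and CASP2 of the Casparian strip at −5.33 (camera adjusted p = 5.80e-06, and adjusted p = 0.314 with an estimated correlation). Of the 5 genes of replication-coupled histone H3.1, 4 fell (adjusted over the list alone, 4), with a median of −3.41 (camera adjusted p = 0.00376, and adjusted p = 0.415 with an estimated correlation). In the cell cycle list 19 fell and 9 rose of 35 (adjusted over the list alone, 20 and 9). The mitotic cyclin gene CYCB1;2 was at −2.88, while MCM5 of the replicative helicase rose by 4.31 (camera adjusted p = 0.0256, and adjusted p = 0.672 with an estimated correlation).

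Genes of the silencing machinery rose in 20 of 34 cases and fell in 5 (adjusted over the list alone, 20 and 5), with VIM1, a methylation maintenance factor, at 1.99, RDR2 at 1.69 and the DNA demethylase ROS1 at −2.55 (camera adjusted p = 0.0251, and adjusted p = 0.524 with an estimated correlation). The remaining 9 lists were not called by camera in LHS. Senescence genes rose in 5 and fell in 8 of 19 tested cases (adjusted p = 0.707), and their median of 0.08, or 0 with SAG13 at its bound, differed in sign from the mean of −0.46. Abscisic acid genes rose in 6 and fell in 7 of 19 (adjusted p = 0.238), reactive oxygen genes in 11 and 6 of 18 (adjusted p = 0.0822), and salicylic acid genes in 6 and 4 of 18 (adjusted p = 0.652). Jasmonic acid genes rose in 5 and fell in 5 of 14 (adjusted p = 0.992, with a camera direction of down beside a median of 0.11 and a mean of 0.05), and clock genes rose in 3 and fell in 4 of 14 (adjusted p = 0.486). Of 12 auxin genes 5 fell, of 5 stomatal lineage genes 2 fell, and of 10 seed genes 4 fell, with adjusted p = 0.186, 0.113 and 0.121 by camera. Adjusted over the list alone, 1 seed gene and 4 auxin genes fell, and 6 senescence genes rose and 8 fell. In the others of these 9 the counts adjusted over the list alone equalled those over all loci. Without CTRL replicate 1, 5 clock genes rose and 4 fell, and without CTRL replicate 2, 2 rose and 7 fell. In the same order 6 and 1 seed genes and 6 and 3 silencing genes fell.

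In all, 8569 gene loci rose and 8179 fell in LHS against CTRL, 68.0% of the 24624 tested, and 11222 of them differed at least 2-fold as well. The share of calls that rose was 51.2%, but 49.6% with TMM scaling, 49.9% with edgeR and 49.8% with DESeq2, so the balance of directions depends on the scaling. The largest falls of named genes included BGLU21, a root beta-glucosidase, from 5904 ± 390.1 to 28.8 ± 13.8 and MYBL2, a repressor of anthocyanin synthesis, from 1909 ± 1600 to 7.55 ± 2.07 (SD, n = 2 each).

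**Figure D2:**
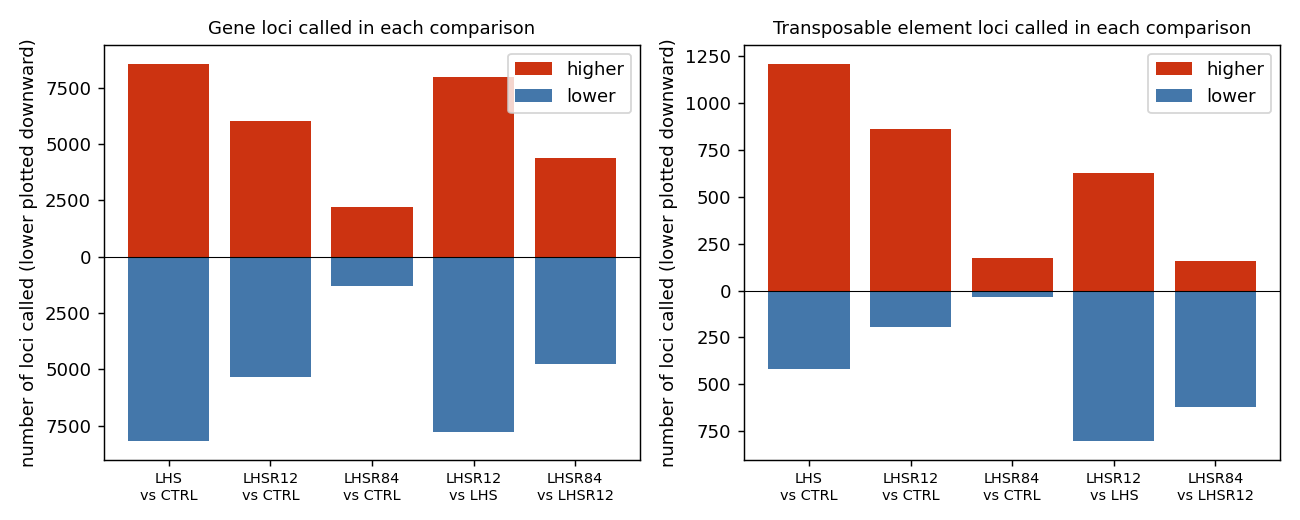
Number of gene loci (left) and transposable element loci (right) called higher (upward) or lower (downward) in each comparison. Gene loci number 8569 higher and 8179 lower in LHS against CTRL, and 2201 and 1311 in LHSR84 against CTRL.

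After 12 h of recovery, LHSR12 against CTRL showed many heat, immune and senescence genes raised, many cell cycle genes lowered, and clock genes changed in both directions. PR1, a salicylic acid marker, was at 0.536 ± 0.759 scaled reads in CTRL and 1006 ± 22.1 in LHSR12 (SD, n = 2 each). PR1 had 1 read over both CTRL libraries, and its ratio was 1681 (95% counting interval 302 to 66430). The morning clock gene LHY went from 82.5 ± 34.7 to 13170 ± 945, and SAG29, a sugar transporter gene raised in senescence, from 88.3 ± 3.49 to 5748 ± 349.6. The blue-light receptor gene FKF1 went from 2661 ± 708 to 10.02 ± 4.42.

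Of the small heat shock protein genes, 15 of 16 were higher in LHSR12 than in CTRL (adjusted over the list alone, 15 higher and 1 lower), with a median of 6.94 (camera adjusted p = 2.76e-09, and adjusted p = 0.362 with an estimated correlation). HSP22-ER was 9.20 and HSP21 8.54 above CTRL on the log2 scale, HSP101 3.47 and HSFA2 1.87. Large chaperones were higher in 9 and lower in 1 of 14 cases (adjusted over the list alone, 9 and 3, and without CTRL replicate 1, 8 and 5), with camera adjusted p = 0.0184 and adjusted p = 0.607 with an estimated correlation. Endoplasmic reticulum stress genes were higher in 7 and lower in 1 of 18 cases (adjusted over the list alone, 7 and 1, without CTRL replicate 1, 7 and 4, and without CTRL replicate 2, 14 and 1), with camera adjusted p = 0.0425 and adjusted p = 0.607 with an estimated correlation. Heat shock factors were higher in 7 and lower in 4 of 20 cases and were not called as a list (camera adjusted p = 0.316). The 8 ONSEN copies were all higher (adjusted over the list alone, 8), with a median of 9.57 (camera adjusted p = 7.56e-08, and adjusted p = 0.362 with an estimated correlation). SDC was 4.97 above CTRL.

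Salicylic acid and immune genes were higher in 15 of 18 cases (adjusted over the list alone, 15), with a median of 2.21 (camera adjusted p = 3.32e-07, and adjusted p = 0.362 with an estimated correlation). PR2 was at 3.64 ± 0.598 in CTRL and 805 ± 15.3 in LHSR12, and the transcription factor gene WRKY70 at 66.9 ± 12.7 and 1650 ± 199 (SD, n = 2 each). Further large rises were in CYP71A13 of camalexin synthesis, LURP1 and the ankyrin repeat gene ANK, with 2 CTRL reads each and ratios of 1744 (483 to 14410), 1152 (319 to 9514) and 1055 (292 to 8712). WRKY38 was at 0 in both CTRL libraries and at least 20.6-fold higher in LHSR12. Reactive oxygen genes were higher in 14 and lower in 2 of 18 cases (adjusted over the list alone, 14 and 2), with APX2 10.12 and the catalase gene CAT2 2.28 above CTRL (camera adjusted p = 0.000241, and adjusted p = 0.314 with an estimated correlation). Senescence genes were higher in 11 and lower in 4 of 19 cases (adjusted over the list alone, 11 and 4), with a median of 0.80 (camera adjusted p = 0.0269, and adjusted p = 0.519 with an estimated correlation). SAG13 was at 0 in both CTRL libraries and at least 193-fold higher in LHSR12, and the senescence regulator NAP was 5.15 above CTRL.

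Photosynthesis genes were lower in 47 of 52 cases in LHSR12 (adjusted over the list alone, 49 lower and 1 higher), with LHCB1.4 at −8.42 and the ferredoxin reductase gene FNR2 at −3.86 (camera adjusted p = 1.74e-17, and adjusted p = 0.409 with an estimated correlation). Chlorophyll synthesis genes were lower in 9 and higher in 3 of 15 cases (adjusted over the list alone, 10 and 3). PORB was at −6.79, while HEMA1, an early enzyme of the pathway, was at 1.06 (camera adjusted p = 0.00889, and adjusted p = 0.409 with an estimated correlation). Cell cycle genes were lower in 26 of 35 cases (adjusted over the list alone, 29 lower and 1 higher), with the mitotic genes CDC20.1 at −2.85 and CYCB1;2 at −2.57 (camera adjusted p = 5.80e-10, and adjusted p = 0.422 with an estimated correlation). Of the histone H3.1 genes 4 of 5 were lower (adjusted over the list alone, 4; camera adjusted p = 0.0277, and adjusted p = 0.519 with an estimated correlation). Silencing genes were lower in 13 and higher in 3 of 34 cases (adjusted over the list alone, 13 and 3), with a median of −0.27, and without CTRL replicate 1 the counts were 15 and 2, without CTRL replicate 2 10 and 1 (camera adjusted p = 0.0205, and adjusted p = 0.519 with an estimated correlation). Root markers were lower in 10 and higher in 2 of 21 cases (adjusted over the list alone, 12 and 2), and the higher ones were SCR and SHR, regulators of root ground tissue (camera adjusted p = 0.00276, and adjusted p = 0.362 with an estimated correlation).

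Of 14 clock genes, 10 were lower and 4 higher in LHSR12 than in CTRL (adjusted over the list alone, 10 and 4), and the list was called lower (camera adjusted p = 0.00167, and adjusted p = 0.451 with an estimated correlation). The 4 higher genes were CCA1, LHY, RVE8 and PRR9, whose transcripts peak around dawn or in the morning. TOC1, an evening gene, went from 7311 ± 969 to 762 ± 41.2 (SD, n = 2 each). Not called by camera were abscisic acid genes (10 higher and 6 lower of 19, adjusted p = 0.598, with a median of 0.70 and a mean of −0.06) and jasmonic acid genes (4 and 3 of 14, adjusted p = 0.643). Neither were auxin genes (4 and 1 of 12, adjusted p = 0.903), stomatal lineage genes (0 and 2 of 5, adjusted p = 0.283) and seed genes (1 and 4 of 10, adjusted p = 0.0585). Without CTRL replicate 1 the auxin counts were 2 and 1 and the seed counts 1 and 5. Without CTRL replicate 2 they were 4 and 2, those of the stomatal genes 1 and 1, and those of the seed genes 1 and 2. Counts adjusted over the list alone equalled those with all libraries. The median of the jasmonic acid genes was 0.31, or 0.11 with genes at 0 placed at their bound. In all, 5999 gene loci were higher and 5343 lower in LHSR12 than in CTRL, 46.1% of those tested, and 6655 of these also differed at least 2-fold. The share of calls that were higher was 52.9%, and 49.7% with DESeq2.

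**Figure D3:**
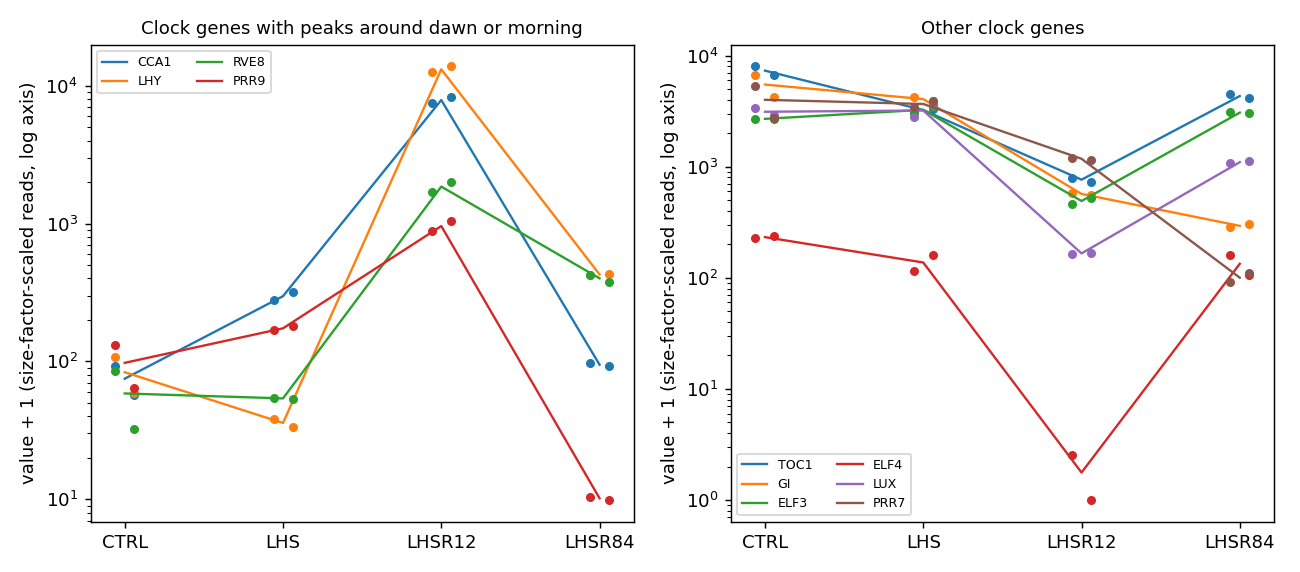
Scaled reads plus 1, on a log axis, of clock genes whose transcripts peak around dawn or in the morning (left) and of other clock genes (right) in the 4 groups. Points are the 2 libraries of each group and lines join the group means. LHY stands at 82.5 in CTRL, 34.8 in LHS, 13170 in LHSR12 and 427 in LHSR84.

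After 84 h of recovery, LHSR84 seedlings still differed from CTRL in ONSEN, light-harvesting and immune genes, while small heat shock protein genes had come closer to CTRL. The light-harvesting gene LHCB1.1 was at 71890 ± 39130 scaled reads in CTRL and 825 ± 207 in LHSR84, and ONSEN-1 at 13.5 ± 3.72 and 6422 ± 1645 (SD, n = 2 each). PDF1.2A, a defensin gene of the jasmonate and ethylene response, was at 0 in every library of the other groups and at 303 ± 52.0 in LHSR84, at least 83.1-fold higher than in CTRL. HSP21 was at 28.3 ± 13.5, not called against 14.1 ± 2.76 in CTRL (log2 fold change 0.88, limma adjusted p = 0.104).

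All 8 ONSEN copies remained higher in LHSR84 than in CTRL (adjusted over the list alone, 8), with a median of 7.79 (camera adjusted p = 6.11e-15, and adjusted p = 0.314 with an estimated correlation). Small heat shock protein genes were higher in 9 of 16 cases (adjusted over the list alone, 14), with a median of 1.92 (camera adjusted p = 1.92e-07, and adjusted p = 0.401 with an estimated correlation). Without CTRL replicate 1 the count was 6, and without CTRL replicate 2 it was 14. Large chaperones were higher in 6 of 14 cases (adjusted over the list alone, 6; camera adjusted p = 0.000694, and adjusted p = 0.519 with an estimated correlation), with HSA32 at 1.25 and HSP101 at 1.27. HSFA2 was 1.92 and SDC 1.83 above CTRL. The call of HSP101 was lost without either LHS library, either LHSR12 library or LHSR84 replicate 2. That of SDC was lost without either LHSR12 library or LHSR84 replicate 2, and that of HSA32 without LHSR84 replicate 1. HSP21 was called without LHSR84 replicate 2 (1.37).

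Photosynthesis genes were lower in 33 and higher in 3 of 52 cases in LHSR84 (adjusted over the list alone, 35 and 5), with a median of −1.29 (camera adjusted p = 4.76e-17, and adjusted p = 0.409 with an estimated correlation). The list was divided after the values were seen. Of 19 light-harvesting genes 17 were lower and 1, LHCB4.3, was higher (3.03), and of 25 photosystem and electron transport genes 16 were lower. Of 8 carbon fixation genes 2 were higher and none was lower at an adjusted p of 0.05 in limma. These were RBCS1B (0.78) and RBCS2B (0.77), and the call of RBCS1B was lost without any single library except CTRL replicate 2. Light-harvesting genes took 8.42% and 5.35% of the gene-locus sum in the CTRL libraries, 0.538% and 0.640% in LHS, 1.39% and 1.62% in LHSR12, and 1.03% and 1.19% in LHSR84. Carbon fixation genes took 2.69% and 2.72%, 0.876% and 0.927%, 1.57% and 1.65%, and 3.52% and 3.28% in the same order. LHCB1 and RBCS copies are nearly identical in sequence, so values of single copies are uncertain.

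**Figure D4:**
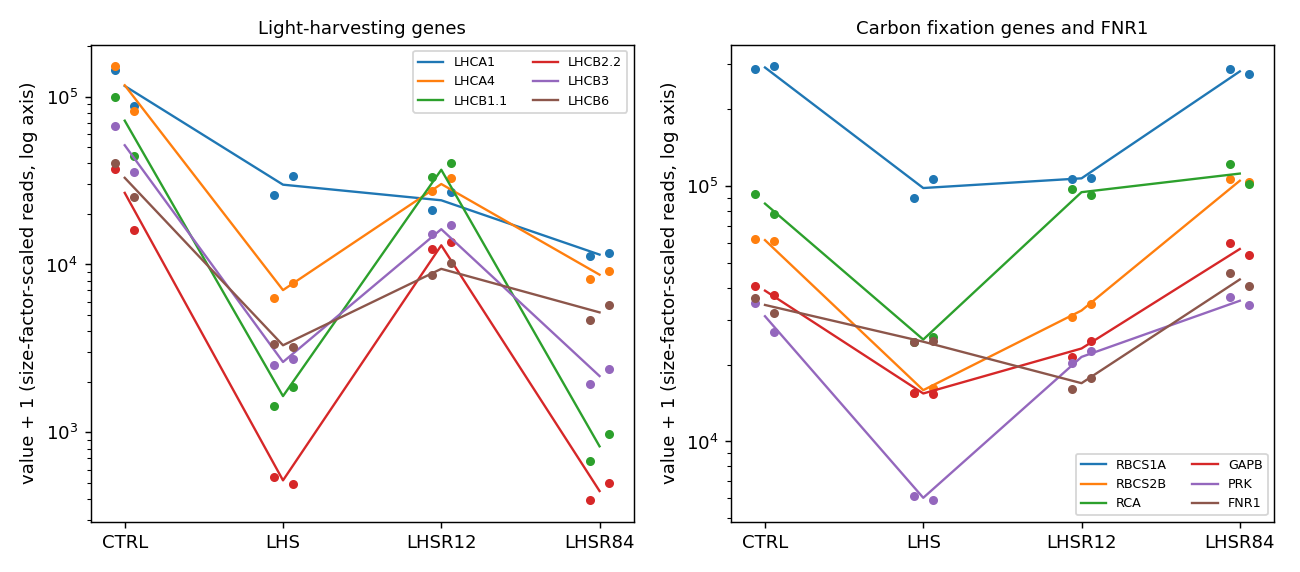
Scaled reads plus 1, on a log axis, of 6 light-harvesting genes (left) and of carbon fixation genes with FNR1 (right) in the 4 groups. Points are the 2 libraries of each group and lines join the group means. LHCB1.1 stands at 71890 in CTRL and 825 in LHSR84, and RBCS2B at 61410 and 104900.

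Salicylic acid and immune genes were higher in 14 of 18 cases and lower in 1 in LHSR84 (adjusted over the list alone, 14 and 1), with a median of 2.04, or 1.68 with WRKY38 at its bound (camera adjusted p = 1.29e-10, and adjusted p = 0.314 with an estimated correlation). PR1 was at 614 ± 258 and LURP1 at 2912 ± 68.6 (SD, n = 2 each), with ratios to CTRL of 1052 (95% counting interval 189 to 41600) and 2436 (674 to 20120). The lower gene was ALD1 (−1.90), whose call was lost without any single library except CTRL replicate 2. It was also lost with a pseudocount of 0.1, without the filter on low values, with the replicate number as a block, and with DESeq2 and edgeR. Jasmonic acid genes were higher in 9 of 14 cases (adjusted over the list alone, 11), with a median of 1.39, or 0.92 with genes at 0 in CTRL placed at their bound (camera adjusted p = 1.20e-07, and adjusted p = 0.347 with an estimated correlation). JAZ9, a repressor of jasmonate signalling, was at 2.45. Abscisic acid and dehydration genes were lower in 8 and higher in 1 of 19 cases (adjusted over the list alone, 10 and 1), with RD29B at −3.93 and KIN2 at −2.14 (camera adjusted p = 8.69e-06, and adjusted p = 0.314 with an estimated correlation). Reactive oxygen genes were higher in 6 and lower in 1 of 18 cases (adjusted over the list alone, 6 and 2; camera adjusted p = 0.0119, and adjusted p = 0.347 with an estimated correlation). Senescence genes were higher in 8 and lower in 2 of 19 cases (adjusted over the list alone, 9 and 3), with the regulators NAP at 3.54 and ORE1 at 2.05 (camera adjusted p = 0.00592, and adjusted p = 0.475 with an estimated correlation). Without CTRL replicate 1, 10 were higher and 0 lower, and without CTRL replicate 2, 7 and 5.

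Clock genes were lower in 8 and higher in 2 of 14 cases in LHSR84 (adjusted over the list alone, 8 and 3), with PRR7 at −5.25 (camera adjusted p = 0.00251, and adjusted p = 0.453 with an estimated correlation). Chlorophyll synthesis genes were lower in 5 of 15 cases (adjusted over the list alone, 8 lower and 1 higher; camera adjusted p = 0.00107, and adjusted p = 0.362 with an estimated correlation). Root markers were lower in 4 and higher in 1 of 21 cases (adjusted over the list alone, 6 and 1, without CTRL replicate 1, 2 and 0, and without CTRL replicate 2, 3 and 0), with camera adjusted p = 0.0172 and adjusted p = 0.409 with an estimated correlation. The 4 lower genes were CASP2, CASP5, TIP2;3 and PLT1 and the higher one was SCR, all given after their values were seen. Auxin genes were lower in 3 of 12 cases (adjusted over the list alone, 5), and these were IAA3, IAA29 and GH3.6 (camera adjusted p = 0.00285, and adjusted p = 0.362 with an estimated correlation). None of the 35 cell cycle genes was called by limma (adjusted over the list alone, 0, and 0 by edgeR on 7 libraries, with 0 higher and 8 lower at an unadjusted p below 0.05, and 1 called lower without CTRL replicate 1), although camera called the list lower with a median of −0.28 (adjusted p = 0.00115, and adjusted p = 0.581 with an estimated correlation). Heat shock factors (4 higher and 1 lower of 20, adjusted over the list alone 5 and 1, 3 and 0 without CTRL replicate 1, 5 and 2 without CTRL replicate 2, camera adjusted p = 0.155), endoplasmic reticulum stress genes (1 and 0 of 18, 0 and 1 without CTRL replicate 1, 5 and 0 without CTRL replicate 2, adjusted p = 0.333) and silencing genes (2 and 0 of 34, over the list alone 1 and 0, 1 and 1 without CTRL replicate 1, 2 and 1 without CTRL replicate 2, adjusted p = 0.826) were not called as lists. Neither were histone H3.1 genes (0 and 0 of 5, adjusted p = 0.264), stomatal genes (1 and 0 of 5, adjusted p = 0.693, with a median of −0.09 and a mean of 0.15) and seed genes (1 and 1 of 10, over the list alone 1 and 2, and 0 and 2 without CTRL replicate 1, adjusted p = 0.345).

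In all, 2201 gene loci were higher and 1311 lower in LHSR84 than in CTRL, 14.3% of those tested. This count of 3512 was 2036 with a minimum of 2-fold, 1644 at an adjusted p of 0.01, 276 in a fit of only these 2 groups, and between 1405 and 2276 without any single LHS, LHSR12 or LHSR84 library. In the fit of only LHSR84 and CTRL, the calls of LURP1, PR1, RLP38, ANK, PR2, CIPK20, LHCB1.1, LHCB1.2, LHCB2.2, PRR7, HSP17.6C-CI, HSP17.8-CI, RBCS1B, ALD1, HSP101, HSFA2, HSA32, SDC and of ONSEN copies 2, 4, 5, 6 and 8 were lost. The largest fall of a named gene was in CIPK20, a protein kinase gene, from 1572 ± 665 to 5.81 ± 6.82 (SD, n = 2 each).

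**Figure D5:**
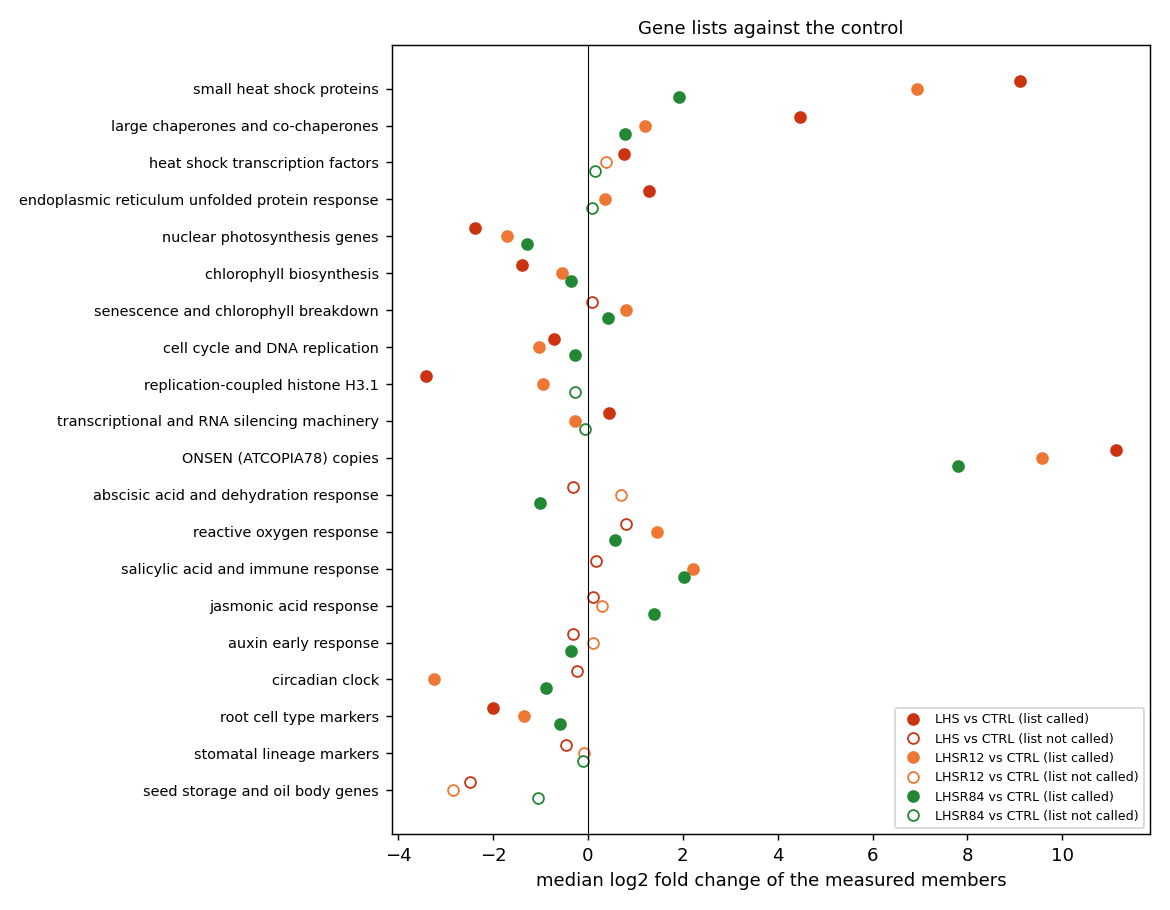
Median log2 fold change against CTRL of the tested members of each of the 20 gene lists in LHS, LHSR12 and LHSR84. Filled points are lists called by camera with the preset correlation, open points are lists not called. Small heat shock proteins fall from 9.11 in LHS to 1.92 in LHSR84, and salicylic acid genes stand at 0.17, 2.21 and 2.04.

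The direct comparison of LHSR12 with LHS asks what changed within 12 h of the end of heat. Most genes of the large chaperone, small heat shock protein and ONSEN lists fell, and most salicylic acid genes rose. HSFA2 fell from 3201 ± 4.14 to 53.5 ± 12.9 scaled reads and ROF2 from 203200 ± 37170 to 8120 ± 1574, while LHCB2.3 rose from 39.3 ± 5.35 to 3496 ± 799.5 (SD, n = 2 each). All 14 large chaperones fell (adjusted over the list alone, 14; camera adjusted p = 3.36e-06, and adjusted p = 0.453 with an estimated correlation). Small heat shock protein genes fell in 12 and rose in 2 of 16 cases (adjusted over the list alone, 12 and 2; camera adjusted p = 0.00271, and adjusted p = 0.519 with an estimated correlation). The risers were peroxisomal HSP15.7-Px (1.11) and HSP15.4 (0.79), and the call of HSP15.4 was lost without either LHS library, without either LHSR12 library, and with DESeq2 and edgeR. Heat shock factors rose in 5 and fell in 11 of 20 cases (adjusted over the list alone, 6 and 11) and were not called as a list (camera adjusted p = 0.120), with HSFA6A at 5.52 and HSFA6B at −6.10. Of the ONSEN copies 7 of 8 fell (adjusted over the list alone, 8), with a median of −1.44 (camera adjusted p = 0.0184, and adjusted p = 0.529 with an estimated correlation). Endoplasmic reticulum stress genes fell in 12 and rose in 2 of 18 cases (adjusted over the list alone, 12 and 2; camera adjusted p = 0.00747, and adjusted p = 0.519 with an estimated correlation).

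Salicylic acid genes rose in 14 of 18 cases between LHS and LHSR12 (adjusted over the list alone, 15), with a median of 2.58 (camera adjusted p = 8.68e-06, and adjusted p = 0.362 with an estimated correlation). Photosynthesis genes rose in 34 and fell in 4 of 52 cases (adjusted over the list alone, 35 and 5; camera adjusted p = 7.49e-05, and adjusted p = 0.586 with an estimated correlation). Root markers rose in 14 and fell in 1 of 21 cases (adjusted over the list alone, 14 and 1), with CASP2 at 3.99 and the root hair gene COBL9 at 3.53 (camera adjusted p = 0.00371, and adjusted p = 0.362 with an estimated correlation). Histone H3.1 genes rose in 4 of 5 cases (adjusted over the list alone, 4; camera adjusted p = 0.00772, and adjusted p = 0.443 with an estimated correlation). Senescence genes rose in 8 and fell in 2 of 19 cases (adjusted over the list alone, 8 and 2; camera adjusted p = 0.0319, and adjusted p = 0.519 with an estimated correlation). Silencing genes fell in 23 and rose in 2 of 34 cases (adjusted over the list alone, 24 and 2), with VIM1 at −2.93 and CLSY1, a chromatin remodeller, at −2.06 (camera adjusted p = 9.44e-05, and adjusted p = 0.409 with an estimated correlation). The risers were the chromatin assembly gene FAS1 (1.02) and the histone methyltransferase gene SUVH6 (0.88). Cell cycle genes fell in 18 and rose in 3 of 35 cases (adjusted over the list alone, 18 and 3; camera adjusted p = 0.00562, and adjusted p = 0.607 with an estimated correlation). Clock genes fell in 10 and rose in 4 of 14 cases (adjusted over the list alone, 10 and 4; camera adjusted p = 0.0165, and adjusted p = 0.519 with an estimated correlation), with FKF1 at −5.97. Not called by camera were chlorophyll synthesis genes (8 rose and 4 fell of 15, adjusted over the list alone 9 and 4, adjusted p = 0.142), abscisic acid genes (10 and 3 of 19, adjusted p = 0.0861) and reactive oxygen genes (7 and 6 of 18, adjusted p = 0.693). Neither were jasmonic acid (6 and 1 of 14, adjusted p = 0.269), auxin (7 and 0 of 12, adjusted p = 0.0738), stomatal (2 and 1 of 5, adjusted p = 0.353) and seed genes (1 and 1 of 10, over the list alone 1 and 0, adjusted p = 0.826). In all, 7965 gene loci rose and 7787 fell, 64.0% of those tested, and 10086 of these also differed at least 2-fold. The share of calls that rose was 50.6%, but 49.6% with edgeR and 49.8% with DESeq2.

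The comparison of LHSR84 with LHSR12 covers the following 72 h of recovery. Most small heat shock protein genes fell further, most cell cycle genes rose and the clock genes changed in both directions. HSP21 fell from 5641 ± 1272 to 28.3 ± 13.5 scaled reads and SAG29 from 5748 ± 349.6 to 50.6 ± 10.3, while PORB rose from 183 ± 6.67 to 7650 ± 988 (SD, n = 2 each). Small heat shock protein genes fell in 14 of 16 cases (adjusted over the list alone, 15; camera adjusted p = 4.50e-09, and adjusted p = 0.362 with an estimated correlation). ONSEN copies fell in 6 of 8 cases (adjusted over the list alone, 7), with a median of −1.74 (camera adjusted p = 0.00296, and adjusted p = 0.519 with an estimated correlation). Cell cycle genes rose in 21 and fell in 1 of 35 cases (adjusted over the list alone, 22 and 1), with CDC20.1 at 2.37 and CYCB1;2 at 2.27 (camera adjusted p = 2.86e-08, and adjusted p = 0.453 with an estimated correlation). The single faller was CYCD3;3 (−0.90), and its call was lost without LHSR12 replicate 1.

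Photosynthesis genes rose in 29 and fell in 10 of 52 cases between LHSR12 and LHSR84 (adjusted over the list alone, 32 and 11; camera adjusted p = 0.000314, and adjusted p = 0.607 with an estimated correlation). In the parts divided after the values were seen, the 10 fallers were light-harvesting genes, such as LHCB1.1 at −5.49, while LHCB1.4 rose by 4.53, and 7 of 8 carbon fixation genes rose. Jasmonic acid genes rose in 9 and fell in 2 of 14 cases (adjusted over the list alone, 10 and 2), with the jasmonate synthesis gene AOC2 at 3.44 (camera adjusted p = 0.00167, and adjusted p = 0.409 with an estimated correlation). Abscisic acid genes fell in 13 and rose in 1 of 19 cases (adjusted over the list alone, 13 and 3), with RD29B at −5.40 and the riser COR15B at 4.55 (camera adjusted p = 0.00119, and adjusted p = 0.362 with an estimated correlation). Reactive oxygen genes fell in 13 and rose in 2 of 18 cases (adjusted over the list alone, 13 and 2; camera adjusted p = 0.00223, and adjusted p = 0.314 with an estimated correlation). Salicylic acid genes fell in 8 and rose in 1 of 18 cases (adjusted over the list alone, 9 and 1; camera adjusted p = 0.0231, and adjusted p = 0.519 with an estimated correlation), and the riser was WRKY54, given after its values were seen. Silencing genes rose in 11 and fell in 2 of 34 cases (adjusted over the list alone, 11 and 2; camera adjusted p = 0.0131, and adjusted p = 0.519 with an estimated correlation). Also called lower were endoplasmic reticulum stress genes (6 lower and 1 higher of 18, camera adjusted p = 0.0269, and adjusted p = 0.584 with an estimated correlation) and auxin genes (6 and 0 of 12, adjusted p = 0.0184, and adjusted p = 0.409 with an estimated correlation), with equal counts adjusted over the list alone. Called higher were root markers (7 higher and 3 lower of 21, over the list alone 8 and 3, adjusted p = 0.0488, and adjusted p = 0.426 with an estimated correlation) and histone H3.1 genes (2 and 0 of 5, over the list alone 4 and 0, adjusted p = 0.0450, and adjusted p = 0.519 with an estimated correlation). All 14 clock genes were called, 8 higher and 6 lower (adjusted over the list alone, 8 and 6), and the list as a whole was not (camera adjusted p = 0.109). Not called as lists either were large chaperones (3 higher and 7 lower of 14, adjusted p = 0.0871), heat shock factors (5 and 6 of 20, adjusted p = 0.573), chlorophyll synthesis genes (7 and 3 of 15, over the list alone 8 and 4, adjusted p = 0.142) and senescence genes (4 and 8 of 19, over the list alone 4 and 9, adjusted p = 0.333). The same held for stomatal genes (2 and 0 of 5, camera adjusted p = 0.113) and seed genes (0 and 0 of 10 by limma, camera adjusted p = 0.160). Of the seed genes, 3 were higher and 1 lower by limma at an unadjusted p below 0.05. In all, 4397 gene loci rose and 4759 fell, 37.2% of those tested. The share of calls that rose was 48.0%, but 51.2% with TMM scaling, 53.6% with edgeR and 52.1% with DESeq2, so which direction was more frequent depends on the scaling. The count of 9156 was 4753 with a minimum of 2-fold, 5256 at an adjusted p of 0.01, and between 4954 and 5703 without any single LHSR12 or LHSR84 library.

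Transposable element loci took a larger share of the reads after heat. Their summed value was 0.590% and 0.631% of that of gene loci in the CTRL libraries, 3.71% and 4.59% in LHS, 2.201% and 1.79% in LHSR12, and 1.11% and 1.00% in LHSR84. Of 3014 element loci tested, 1212 rose and 421 fell in LHS, 862 were higher and 196 lower in LHSR12, and 172 were higher and 34 lower in LHSR84, each against CTRL (112 and 17 in LHSR84 without CTRL replicate 1, 182 and 38 without CTRL replicate 2). A locus at 0 in CTRL could only be called higher against CTRL, which bears on these counts. Loci were divided by identifier alone, and the ONSEN copies have gene identifiers. They thus counted as gene loci in these shares and in the odds ratios below, and held 2.26% and 3.11% of the gene-locus sum in LHS. Pseudogene loci with gene identifiers also counted there, and of 854 tested, 510 rose and 56 fell in LHS. How far the odds ratios depend on this division was not tested. Whether element loci were called higher more often than gene loci depended on the setting and on which loci were counted as tested. In LHS the odds ratio was 1.26 (two-sided Fisher's exact test p = 6.04e-09, which treats loci as independent). Without the filter on low values it was 0.605 over the 6839 element loci then tested and 1.23 over the 3014 of the main test. It was 0.983 with DESeq2 and 1.396 with edgeR (TMM factors) over the loci each of them tested. Over the loci of the main test, where loci they left out count as not called, it was 0.614 and 0.770. In LHSR12 the odds ratio was 1.24 (exact p = 5.53e-07), and without the filter 0.663 over all loci then tested and 1.24 over those of the main test. It was 1.19 with DESeq2 and 1.44 with edgeR over their own loci, and 0.755 and 0.834 over those of the main test. Without CTRL replicate 1 it was 1.09 in LHS and 1.06 in LHSR12 (exact p = 0.0378 and 0.254), and without CTRL replicate 2 it was 1.13 and 1.12 (exact p = 0.00192 and 0.0136). In LHSR84 it was 0.617 (exact p = 4.06e-10). It was below 1 in every other setting for which it was computed, except a fit of only LHSR84 and CTRL, with 2.74. The odds ratio was not computed with a minimum of 2-fold or with rRNA loci left out. As a set, element loci were called higher by camera in LHS (adjusted p = 0.00351, and adjusted p = 0.296 with an estimated correlation) and LHSR12 (adjusted p = 0.00495, and adjusted p = 0.296 with an estimated correlation). They were not called in LHSR84 (camera adjusted p = 0.0813). Between LHS and LHSR12, 630 rose and 803 fell (camera adjusted p = 0.333). Between LHSR12 and LHSR84, 158 rose and 623 fell, and the set was called lower (camera adjusted p = 0.0239, and adjusted p = 0.314 with an estimated correlation). The 20 element loci with the largest gain held 89.2% of the gain in LHS. AT3TE59490 rose by 12.09 in LHS. AT2TE15415 had 1 read over both CTRL libraries, and its ratio in LHS replicate 2 was 12880 (95% counting interval 2311 to 508800). AT4TE10320 and AT1TE71830 were listed at 0 in both LHS libraries, against 332 and 249.9 in the CTRL libraries for the former and 347 and 379 for the latter. With count tests on 7 libraries, fewer element loci were called higher in LHS, 551 with DESeq2 and 718 with edgeR.

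Part of the change seen at the end of heat was still seen in recovery. Of the genes that rose in LHS, 3301 were also higher in LHSR12 and 874 in LHSR84, and of those that fell, 3648 and 948 were also lower. Independent lists would share 2087.6, 765.9, 1774.7 and 435.5 in the same order. Since all comparisons share the CTRL libraries, part of the excess may come from them. The covariance of the log2 fold changes with those of LHS was 1.63 for LHSR12 and 0.52 for LHSR84, against 0.07 in simulated groups without any effect that share the controls. The simulation gave all groups the same spread. The CTRL libraries differed more from each other (median absolute log2 difference 0.25) than those of the other groups (0.15 to 0.16), so 0.07 may be too low. Heat shock and ONSEN genes such as HSFA2, HSA32 and ONSEN-2 were among the 799 genes higher than CTRL in LHS, LHSR12 and LHSR84, while 782 were lower in all of these groups. Of the genes called in LHS, 14100 (84.2%) were not called in LHSR84. Only 14.3% of all genes tested were called in LHSR84 against CTRL, so this share is near that among all genes. A gene not called has not been shown to return to CTRL. In LHSR12, 1739 genes were higher than in CTRL, LHS and LHSR84, among them SAG13, SAG29 and LHY, and 1357 were lower, among them FKF1 and PORB. Of these, 245 are also among the 799 and 157 among the 782. The genes called in the same direction in LHS and LHSR84, 1822 in all, numbered 127 in fits of only the 2 groups compared, 788 at an adjusted p of 0.01, and 755 to 1186 without any single LHS, LHSR12 or LHSR84 library.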

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

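The tests of the light-harvesting pattern, and the scaling and harvest-time tests of the clock pattern, were chosen after the results were seen.

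Some genes were called against CTRL in opposite directions at the end of heat and in recovery. For each of them the difference between the time points was itself called by limma. Genes picked for opposite calls against the same control have large differences by construction, so this is no further support. Of the genes higher in LHS, 591 (6.90%) were lower than CTRL in LHSR12, against 21.7% of all genes tested. Of those lower in LHS, 1065 (13.0%) were higher in LHSR12, against 24.4% of all genes tested. For LHSR84 these counts were 132 (1.54%, against 5.32%) and 694 (8.485%, against 8.94%). In each case the share was below that among all genes tested. The silencing list was higher in LHS and lower in LHSR12 (camera adjusted p = 9.44e-05 for the difference, and adjusted p = 0.409 with an estimated correlation). The silencing genes VIM1 and CLSY1 did so as well, with differences of −2.93 and −2.06 between LHSR12 and LHS, as did the clock gene BOA at −5.60 and the jasmonate synthesis gene AOC2 at −4.38. The anthocyanin gene DFR was lower in LHS and higher in LHSR12, a fitted difference of 8.58. That value also depends on the pseudocount, because DFR was at 2.00 ± 2.83 scaled reads in LHS. In CTRL it was at 128 ± 141 (SD, n = 2 each), so the control libraries differed widely. PR2 was called lower in LHS, at 0.507 ± 0.717 scaled reads against 3.64 ± 0.598 in CTRL (SD, n = 2 each), so this fall rests on few reads. In both recovery groups PR2 was higher than in CTRL, with fitted differences to LHS of 9.15 at 12 h and 7.89 at 84 h. These differences depend on the pseudocount because PR2 was near 0 in LHS. RBOHD, an NADPH oxidase gene, was lower in LHS and higher in both recovery groups, with differences of 1.71 and 2.53. RBCS1B was lower in LHS and higher in LHSR84, a difference of 3.26, and SAG29 was higher in LHS and lower in LHSR84, a difference of −2.05.

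Of 19 light-harvesting genes, 17 were lower in LHSR84 than in CTRL, although 13 had risen from LHS to LHSR12, and 10 fell from LHSR12 to LHSR84. A single control library with high values is argued against, since at least 17 of the 19 genes were called lower with either CTRL library left out. A changed division of reads among near-identical copies would keep their sum if reads with several matches were counted, which is not stated. The sum in the highest LHSR84 library reached 21.1% of that in the lowest CTRL library. This argues against a changed division only if such reads were counted. A different time of day at harvest stays open, since 10 of the 14 clock genes were called between LHSR84 and CTRL and these light-harvesting genes may follow the clock. The treatment itself and the age of the plants stay open as well, untested.

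More transposable element loci rose than fell in LHS. Loci were kept on their mean over all 8 libraries, so those at 0 in CTRL could only be called higher. Those at 0 in LHS could only be called lower. Element loci above 0 numbered 2022 and 2268 in the CTRL libraries and 3627 and 3677 in the LHS libraries. How far this shaped the counts of risers and fallers was not tested. An even background of reads over all loci could not be decided. Of the element loci above 0 in another group, 40.0% were at 0 in both LHS libraries. A sparse background would also leave many loci at 0, and 85.15% of all element loci were at 0 in both LHS libraries. Without the 20 loci with the largest gain, 1192 rose and 421 fell, 2.83 per faller. This could not test whether a few abundant loci gave the pattern, since each locus counts once whatever its abundance. Only with 377 loci set aside would the ratio fall below 2, but this follows from the counts themselves and tests nothing further. Those 20 loci held 89.2% of the summed gain. Reads of genes counted again at elements cannot be told apart from element transcripts, since 16.8% of the rising loci had a gene locus of nearly equal values and positions that would show overlap were not used. Heat acting on the elements stays open as an explanation.

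Clock genes differed between LHSR12 and LHSR84, groups whose stated recovery times lie 72 h apart, and so should fall at a like time of day if heat ended at the same hour. Scaling of the libraries is argued against, since the smaller of both directions still held 6 of the 14 genes. A single deviating library is argued against, since at least 12 of the 14 were called with any of these libraries left out. Harvest at different times of day cannot be told apart from a shift of the clock after heat, as no times of day are given and all 14 genes were called. A clock shifted or reset by heat could give the same values.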

How the results depend on the processing

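DESeq2 and edgeR on the reads of 7 libraries were chosen after the data were seen. So were TMM scaling, scaling on gene loci alone and the alternatives of the element odds ratio. The other alternatives were chosen before. For a table of counts, edgeR with TMM factors on all 8 libraries had been planned as the main test. It was replaced by limma, the test fixed for a table without counts. The planned DESeq2 and edgeR RLE fits of all 8 libraries were not run, because LHS replicate 1 has no recovered reads. Leaving out organelle loci was not run, since the table holds none. No named gene and no list called by camera changed direction in any setting. Fry gave the other direction for 4 lists not called, senescence and jasmonic acid genes in LHS and silencing genes in LHSR84 against CTRL, and seed genes in LHSR12 against LHS. In contrast, the more frequent direction of all calls changed in 4 of the 5 comparisons, as the shares given above show. The counts of calls named in this part stayed within 1.5 times with a pseudocount of 0.1, no filter, rRNA loci left out, TMM scaling and scaling on gene loci alone. The cause of the shifts below was not tested except where fewer samples or a stricter threshold give it by construction.

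At an adjusted p of 0.01, genes called numbered 1644 in LHSR84 against CTRL and 5256 in LHSR84 against LHSR12, element loci called higher in LHSR84 85, and genes called the same way in LHS and LHSR12 4453 and in LHS and LHSR84 788. With a minimum of 2-fold, genes called numbered 6655 in LHSR12 and 2036 in LHSR84 against CTRL, 10086 in LHSR12 against LHS and 4753 in LHSR84 against LHSR12, and the shared genes 3857 and 962. In fits of only the 2 groups compared, LHSR84 against CTRL had 276 genes and 77 higher element loci, and 127 genes were shared with LHS. With 1 library left out, whose lone partner is assumed to vary like the other groups, LHSR84 against CTRL ranged from 1405 to 2276 genes without an LHS, LHSR12 or LHSR84 library and was 3979 without CTRL replicate 2. LHSR84 against LHSR12 ranged from 4954 to 5703 without an LHSR12 or LHSR84 library, up to 10320 without CTRL replicate 2. Genes shared by LHS and LHSR84 ranged from 755 to 1186 without an LHS, LHSR12 or LHSR84 library, up to 2269 without CTRL replicate 2. Element loci higher in LHSR84 numbered 91 without either LHSR84 library, 112 without CTRL replicate 1 and 182 without CTRL replicate 2. On the reads of 7 libraries, DESeq2 called 551, 467 and 112 element loci higher in LHS, LHSR12 and LHSR84, edgeR with RLE factors 724, 564 and 112, and edgeR with TMM factors 718 and 564 in LHS and LHSR12.

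With the replicate number as a block, LHS, LHSR12 and LHSR84 against CTRL had 16618, 11128 and 3302 genes. Correlations across genes of the replicate differences of 2 groups lay between −0.18 and 0.17. They show no strong shared effect of the replicate number. With 1 replicate difference per group, they cannot tell whether the libraries were paired. An estimated correlation ended 67 list calls and fry 6, while fry made 16 further ones. Of named genes, 24 lost their call in fits of only 2 groups, PLT1 in LHSR12 against LHS and the others in LHSR84 against CTRL, as named above. With DESeq2 and with edgeR 3 were lost, ALD1 in LHSR84 against CTRL and HSP15.4 and PLT1 in LHSR12 against LHS. ALD1 alone was lost with a pseudocount of 0.1, with no filter and with the block. Without 1 library, between 0 (CTRL replicate 2) and 12 (LHSR12 replicate 1) were lost, among them PETE2 and PLT1 in LHSR12 against LHS, HSP17.6C-CI and HSP17.8-CI in LHSR84 against CTRL, and CAT3 and ONSEN-3 in LHSR84 against LHSR12. The block also made seed genes a called list in LHSR12 against CTRL. In simulated libraries, 90% of loci changed 4-fold were called by DESeq2 and by edgeR on 7 libraries, and 100% by limma on 8. The sets of libraries differ and depth was not varied, so these shares neither compare the tests nor show an effect of depth.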

Other observations

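Of 854 tested loci annotated as pseudogenes, 510 rose and 56 fell in LHS against CTRL, with a median log2 fold change of 2.09, and 471 were higher and 29 lower in LHSR12. In LHSR84 60 were higher and 4 lower, and 382 fell and 24 rose between LHSR12 and LHSR84. Protein-coding loci rose in 7754 and fell in 7894 of 22797 cases in LHS. Loci of microRNA precursors rose in 40 and fell in 20 of 112 cases in LHS, and were lower in 24 and higher in 3 in LHSR12. Whether these classes differ was not tested, and these counts were looked at after the data were seen.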
